A study of Mus musculus with 10 samples.

How the data were processed

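Total RNA from the hippocampus of 10 adult mice, 5 per group, was amplified and labelled with Cy3 with an Agilent 1-colour kit and read on Agilent mouse arrays, per the labels' protocols. Images were quantified with Agilent Feature Extraction 10.7, per the submitters' processing notes. The scanner files hold spot brightness as intensity on a linear scale, deposited before any normalization between arrays; the processed intensity was background-subtracted and detrended within each array, with surrogate values near background, per the file headers. The series value table holds log2 values, 1 per probe, that the authors deposited without stating how they were made. They matched log2 processed signals after quantile normalization, with slopes of 1.0018 to 1.003 between arrays and column medians of 7.0334 to 7.0337, so that their scale and direction are known, no centring was seen, and the software remains unstated.

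Log2 of the processed signal was taken relative to each array's 75th percentile over the 41174 non-control probes. Spots marked as non-uniform or as population outliers were left out, 68 to 129 per array, and no spot was saturated. Spots of a probe were averaged. A probe entered if it was well above background on at least 3 of the 5 arrays of at least 1 group, and 30977 did. Each gene symbol was represented by its entering probe with the highest mean. Of the called genes with several entering probes, 305 of 1319 had probes of opposite sign. Probes were named through the RefSeq table of assembly GRCm38.p6: 27668 by their accession, 85 by another listed accession and 5993 by symbol or a single synonym, while 7428 kept the name in the files. Positions are those of the probes in the files, on mm9, and no genome sequence was used here.

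Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) on all 10 arrays, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. For 36 gene lists fixed from textbook knowledge before the data were examined, with at least 5 measured genes each, camera was run with the preset correlation of 0.01, with an estimated correlation, and beside fry, with adjustment over the lists. Named genes were chosen by a rule also fixed before the data were examined: the 12 higher and 12 lower called genes with the largest fold changes, leaving out features without an ordinary symbol, the 4 members with the smallest p of each list discussed, and a fixed set of genes that holds Esr1, Esr2, Cyp19a1, Bdnf, Gfap, Mbp, Ttr, Xist and Ddx3y. Some items that this rule takes are not reported here. The genes of other tissues given per array (Alb, Ahsg, Fgb, Fabp1, Th, Ddc, Hcrt, Prl and Gh), the Y-linked genes besides Ddx3y, and the immunoglobulin probes were chosen after their values were seen.

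The alternatives were slide as a fixed or random block, slide 2 alone, the replicate number as a block, normexp background correction with an offset of 50, quantile normalization, the value table, other filters on dim probes, other ways of joining probes, an intensity trend with a robust prior, and leaving out each array. Chosen after seeing the data were the Xist and Y-linked pattern as a covariate, alone or with slide as a block, the arrays with high Xist alone, the arrays without high liver transcripts alone, the mean of the thalamic list as a covariate, and normexp centred on the median gene. Slides were scanned separately, so slide and scan are the same batch. No 2 arrays were duplicates: the SD of the log2 difference between arrays of a group was 0.444 to 0.722.

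The test was tested on simulated data for this comparison of 5 with 5 arrays, with 20020 genes and 200 of them changed. At log2 fold changes of 0.5, 1 and 2 it recovered 22.4%, 64.2% and 93.9%, with 10 wrong calls among 130, and with nothing planted it made 1 call. The planted list was called, and 0 of 35 random lists were. Genes were simulated independently of each other, without differences of slide or tissue. The simulation therefore does not test the counts under such differences, nor list calls where genes vary together. In the lists called here, the estimated correlation between genes ran from -0.0538 to 0.75.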

Results

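Gene expression was measured in the hippocampus of 10 adult offspring of ICR mice, an outbred laboratory stock. In the high estradiol group (HE), pregnant dams had received oral estradiol valerate, an ester that releases estradiol, at 100 µg/kg/day from E5.5 to E11.5, in days of gestation. In the control group (NC), dams had received the corn oil vehicle. Each group held 5 arrays, 1 per animal, and all 10 animals were labelled male. The labels do not give the litter of any animal, so p-values measure the spread between these animals only. Signals were read on 1-colour Cy3 arrays with probes for most mouse genes. The 75th percentile of the signal ranged from 899 to 1289 between arrays, and 70.3% to 78.8% of probes were well above background. The number of arrays limits the precision. The 10 arrays lay on 3 slides: slide 1 held NC 1 to NC 4, slide 2 held NC 5, HE 1 and HE 2, and slide 3 held HE 3 to HE 5. Signals are given below as log2 values relative to each array's 75th percentile.

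Before the groups were compared, the sex label was checked with Xist, the RNA made from the inactive X chromosome, and with 4 Y-linked genes. The signals did not match the male label on 7 of the 10 arrays, chosen as such after their values were seen. On NC 1 to NC 4 and HE 1 to HE 3, Xist lay between 3.20 and 4.44, while Ddx3y lay between -9.32 and -5.54 and Uty between -9.20 and -8.19. On NC 5, HE 4 and HE 5, Xist lay between -7.26 and -4.53, Ddx3y between 1.08 and 1.38, and Eif2s3y between 0.30 and 0.50. The groups therefore held 4 and 3 arrays with high Xist, respectively, and the animals are called "labelled male" here. Whether the sex labels are wrong or samples were exchanged with other animals was not tested; an exchange among these 10 would leave 7 arrays unmatched. Ddx3y was well above background on 2 arrays of each group and did not enter the test. Xist itself differed by less than its spread (log2 fold change -2.71 ± 2.59 SE, adjusted p = 0.480). On slide 2, the NC array had high Y-linked signals and both HE arrays had high Xist, so that the group difference on this slide is also a difference in this pattern. All arrays of slide 1 had high Xist. A fit with slide and this pattern together therefore takes the pattern's effect from slide 3 alone, as HE 3 against HE 4 and HE 5.

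**Figure D1:**
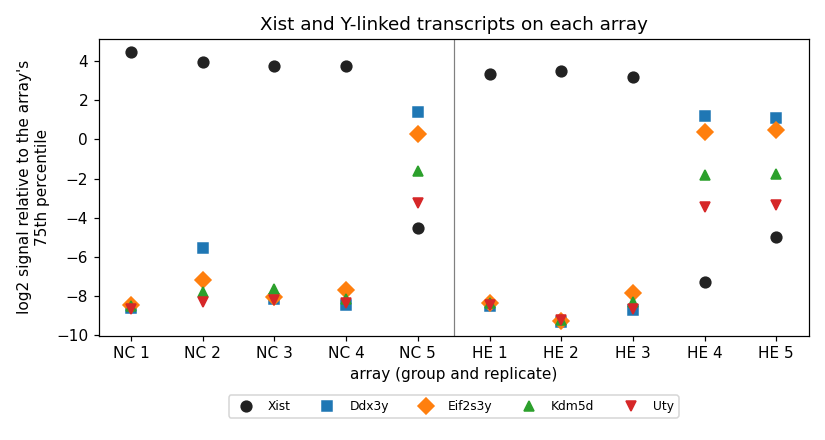
Log2 signal of Xist and of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty on each of the 10 arrays, relative to the array's 75th percentile. Xist lies above 3 on 7 arrays and below -4 on NC 5, HE 4 and HE 5.

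The comparison of HE with NC asks how maternal estradiol excess in early gestation relates to expression in the adult hippocampus. Of the markers fixed for each group, 11 of 20 thalamus and habenula genes and 13 of 23 myelin genes fell in HE, while 8 of 33 synaptic, 5 of 14 CA1 and 6 of 25 interneuron genes rose. Tcf7l2, a transcription factor of thalamic neurons, fell by 2.61 on the log2 scale, and Ermn, a myelin-sheath protein, fell by 1.42. Nptx2, a secreted synaptic pentraxin, rose by 1.6. In all, 4030 of 20065 genes passed the limma test at an adjusted p under 0.05, 1369 higher and 2661 lower in HE. The higher genes made up 34.0% of these calls, but 44.8% after quantile normalization (1930 higher and 2375 lower). The 5 HE and 5 NC arrays did not overlap for 3299 genes, or 16.4%, where chance gives 0.79%. With slide as a block, which leaves only the difference within slide 2, 185 genes passed, 104 higher and 81 lower, and with normexp background correction 8725 did, 1860 higher and 6865 lower. On the 7 arrays with high Xist alone, 96 genes passed, 10 higher and 86 lower. Among these 7 no slide holds both groups, so slide and group cannot be told apart there.

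**Figure D2:**
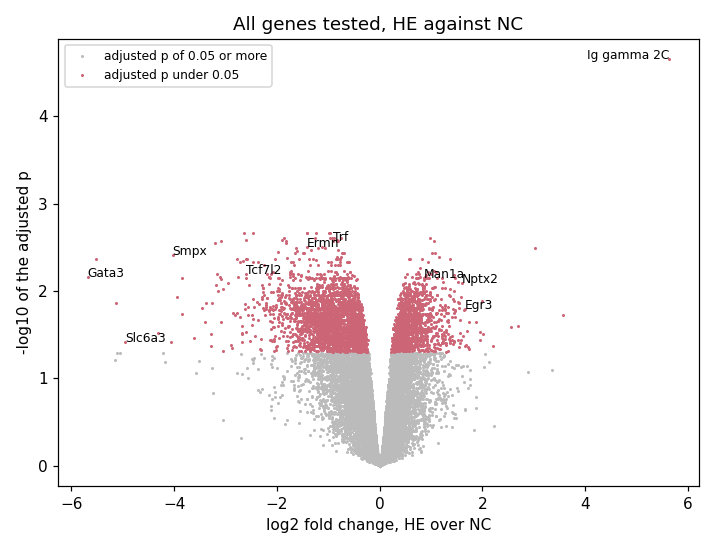
Log2 fold change of HE over NC (x axis) against -log10 of the adjusted p (y axis) for the 20065 genes tested, with named genes marked and genes passing the test in red. Gata3 (fitted value -5.69) lies farthest to the left, and the immunoglobulin gamma 2C probe (fitted value 5.64) lies alone at the top right.

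Several of the 12 called genes with the largest fitted falls are known from midbrain, hypothalamus or thalamus. This rank includes signals not well above background in HE. Gata3, a transcription factor of midbrain and hindbrain neurons (probe at chromosome 2, 9778983 to 9779042, mm9), was -2.84 ± 2.07 (SD, n = 5) in NC and was not well above background on any HE array. Where a probe was well above background on no array of a group, only a bound is given. It is taken against the higher of the probe's own signal and the lowest signal well above background. Gata3 was at least 16.0-fold lower on the group mean (limma adjusted p = 0.00689, for the fitted -5.69). It was uneven within NC, at -1.136, -1.657 and -1.225 on NC 2, NC 4 and NC 5, but -5.039 and -5.148 on NC 1 and NC 3. Slc6a3, the dopamine transporter, went from 1.02 ± 3.58 to -3.93 ± 0.59 (adjusted p = 0.0389), but passed in only 11 of 28 alternatives, with log2 fold changes of -6.60 to -2.92 over them. It did not pass without NC 2 (-3.99), NC 4 (-4.05), NC 5 or any 1 HE array (-5.14 to -4.75). Pmch, which encodes melanin-concentrating hormone of the lateral hypothalamus, went from 1.72 ± 1.55 to -2.13 ± 1.52 (adjusted p = 0.0182). Shox2, a thalamic transcription factor, fell by 3.40 (adjusted p = 0.0227) and was well above background on 1 of 5 HE arrays, not passing without NC 5 (-3.10) or HE 1 (-3.11). Smpx, a small muscle protein (chromosome X, 154190370 to 154190429), fell by 4.03 ± 0.49 SE and Adamts19, a metalloprotease, by 3.85 ± 0.59, with 4 and 2 of 5 HE arrays well above background. Both were lower on all 5 HE arrays than on any NC array, and both passed with slide as a block (Smpx with a log2 fold change of -5.47), as none of the other 10 did. Slc6a3 and Pmch had -4.57 and -5.67 with slide as a block. NC 5, the only NC array on slide 2, was the highest NC array for Adamts19 (-1.95), but not for Smpx (-1.37, against -1.09 on NC 3).

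Genes known from liver, though not all from liver alone, were also among the 12. Apoa2, an apolipoprotein, was at least 14.3-fold lower in HE, Fgg, a fibrinogen chain, at least 7.03-fold lower, and Sult3a1, a sulfotransferase, at least 3.18-fold lower. These bounds are for group means, with 4, 4 and 3 of 5 NC arrays well above background. They do not hold for NC 3, at -7.391, -8.236 and -8.393, where the highest HE values were -7.484, -7.526 and -7.261. Sult3a1 was also low on NC 5 (-7.058). Ambp, a plasma protein precursor, fell by 4.07 (adjusted p = 0.0388) and Cyp2f2, a cytochrome P450, by 3.46 (adjusted p = 0.0155), with 1 and 2 of 5 HE arrays well above background. Ambp did not pass without NC 1, NC 2 or NC 4 (-3.71 to -3.49) or any 1 HE array except HE 2 (-4.19 to -3.87), and was -4.97 without NC 3. Fgg did not pass without the same 7 arrays, nor Sult3a1 without any 1 HE array except HE 1. Fitted values, which include signals not well above background, were -5.13, -4.32 and -3.62 for Apoa2, Fgg and Sult3a1. Without NC 3 they were -6.23, -5.37 and -4.43. These levels were uneven within NC, though not in the same way for every gene. Alb, the serum albumin gene, was 0.50, 0.44 and -0.23 on NC 1, NC 2 and NC 4, but -7.93 on NC 3 and -4.82 on NC 5, against -8.77 to -5.70 in HE, and did not pass (adjusted p = 0.0519). On NC 5, by contrast, Apoa2 was -2.29, near its -2.46 on NC 4, and Cyp2f2 was -2.87, above NC 1 and NC 4 (-3.82 and -3.83). Within slide 2, where NC 5 was the control, the differences of Ambp and Cyp2f2 were -1.12 and -3.61. Slc6a3 was likewise uneven in NC, at 4.88 and 4.62 on NC 2 and NC 4 and at -2.38 on NC 1. Without NC 1, NC 2 and NC 4, 2007 genes passed.

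**Figure D3:**
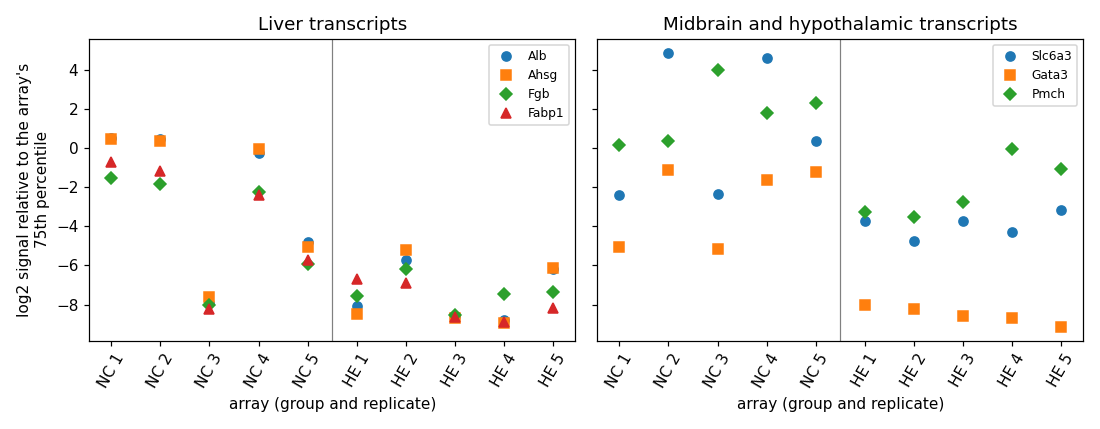
Log2 signal of 4 liver transcripts (left) and 3 midbrain or hypothalamic transcripts (right) on each array, relative to the array's 75th percentile. Alb is near 0 on NC 1, NC 2 and NC 4 and below -4 on every other array, and Gata3 is lower on each HE array than on any NC array.

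Among the 12 called genes with the largest fitted rises, Egr3, an activity-induced transcription factor, rose by 1.66 ± 0.36 SE (adjusted p = 0.0162), and Rprml, a reprimo-like gene, by 1.75 ± 0.43 (adjusted p = 0.0225). Both were higher on all 5 HE arrays than on any NC array and passed with slide as a block (2.92 and 3.27), as none of the other 10 did (Nptx2 1.95, Fst 2.30, Phex 2.10, Ankrd63 2.23, Acvrl1 2.13 and Pnlip 2.53). NC 5, the only NC array on slide 2, was the lowest NC array for Egr3 (-1.09) and Rprml (-2.32). Their values with slide as a block rest on this array. Nptx2 (chromosome 5, 145317905 to 145317964) went from -0.65 ± 0.59 (SD, n = 5) to 0.95 ± 0.20 (adjusted p = 0.00818). Fst, the activin-binding follistatin, rose by 1.57. Without NC 2, Rprml (1.65) and Fst (1.55) did not pass. Phex, an endopeptidase, rose by 2.01 and Ankrd63 by 1.70, but each passed in only 14 of 28 alternatives, and Phex had 0.15 under normexp. Both lost their calls without NC 2, NC 4, NC 5, HE 1 or HE 5, Phex also without HE 2 and Ankrd63 without HE 3 (1.83 to 2.09 and 1.43 to 1.76). Acvrl1, Pnlip and Grap2 rose by 1.68, 1.64 and 1.89 but turned negative under normexp, Pnlip only before centring on the median gene, and Grap2 was well above background on 1 of 5 NC arrays. Grap2 did not pass without NC 2, NC 5 or HE 1 (1.68 to 1.84), nor Acvrl1 without any 1 array except NC 1 and HE 4 (1.33 to 1.76). Snai3 and Tmem45b were well above background on no NC array and were at least 1.27-fold and 1.15-fold higher, also turning negative under normexp. They passed in only 11 of 27 and 8 of 22 alternatives. Snai3 was highest on HE 3 (-4.575, against -8.061 to -5.235 on the other HE arrays). Tmem45b was highest on HE 4 (-4.576, against -7.39 to -5.493), so each small bound leans on 1 array.

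Of 20 measured thalamus and habenula markers, 11 fell, 1 rose and 8 did not pass, and their median log2 fold change was -1.44. Tcf7l2 went from 2.84 ± 0.34 (SD, n = 5) to 0.23 ± 0.87 (adjusted p = 0.00641), and Tnnt1, a troponin of thalamic neurons, from 2.29 ± 0.97 to -0.26 ± 0.36 (adjusted p = 0.00852). Lef1, a transcription factor of Wnt signalling, fell by 1.65, and Rgs16, a G-protein regulator, fell by 1.90. Without HE 1, HE 2, HE 3 or HE 5, the other entering probe of Lef1 stood for the gene, and it fell by 2.43 to 2.50. Adjusted over the list alone, 12 fell and 1 rose. The list was called lower by camera with its preset correlation (adjusted p = 0.00577), but not with an estimated correlation (adjusted p = 0.768). Its median within slide 2, which is also its value with slide as a block, was -2.18. That value rests on NC 5, which had the highest array median of this list (1.233, against -0.161 to 1.043 on the other NC arrays). On the 7 arrays with high Xist the median was -1.37, and with slide as a block and the Xist pattern as a covariate it was -1.56 and the list was not called. None of Tcf7l2, Tnnt1, Lef1 and Rgs16 passed with slide as a block (-3.53, -3.55, -2.37 and -2.37). HE 4 stood apart in its group, with Tcf7l2 at 1.76.

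Of 23 measured myelin and oligodendrocyte genes, 13 fell and none rose (16 fell when adjusted over the list alone), with a median of -0.545. Trf, the iron carrier transferrin, fell from 3.31 ± 0.15 (SD, n = 5) to 2.39 ± 0.12 (adjusted p = 0.00270), Ermn from -0.44 ± 0.24 to -1.85 ± 0.28 (adjusted p = 0.00316), Cnp, a myelin phosphodiesterase, from 4.49 ± 0.16 to 3.72 ± 0.11 (adjusted p = 0.00426), and Mobp from 4.36 ± 0.13 to 3.46 ± 0.26 (adjusted p = 0.00687). Mbp, the main protein of compact myelin, fell by 0.60 (adjusted p = 0.0131), while 1 of its 3 probes differed in sign. All 5 HE arrays lay below every NC array for each of these 5 genes, but none of the 5 passed with slide as a block (-0.69, -1.47, -0.64, -0.76 and -0.52). The list was called lower (adjusted p = 8.46e-07 with the preset, adjusted p = 0.586 with an estimated correlation). Its median was -0.434 within slide 2. With normexp centred on the median gene the median was -0.255 and the list was not called. With the thalamic mean as a covariate the median was -0.49 and the list was called. Of 12 oligodendrocyte precursor markers, 1 fell, and their median was 0.0761.

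**Figure D4:**
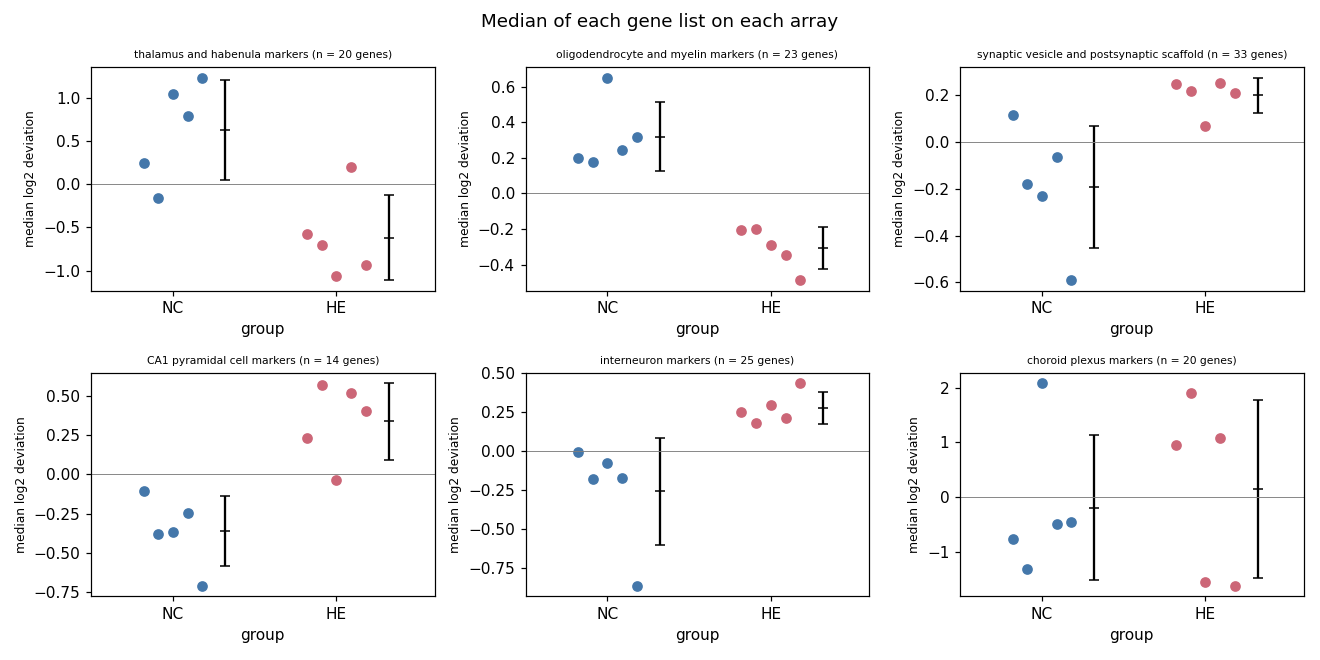
Median log2 deviation of 6 gene lists on each array (y axis) by group (x axis), each gene taken relative to its mean over the 10 arrays; points are arrays and bars are the mean ± SD of 5 arrays. The myelin medians do not overlap between groups (0.177 to 0.651 in NC, -0.489 to -0.199 in HE), whereas those of choroid plexus markers do.

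Of 33 measured genes of the synaptic vesicle and postsynaptic scaffold, 8 rose and none fell (15 rose when adjusted over the list alone), with a median of 0.417. Nlgn2, an adhesion protein of inhibitory synapses, rose from 1.99 ± 0.28 (SD, n = 5) to 2.58 ± 0.10 (adjusted p = 0.0182). Dlg2 rose by 0.82, with 1 of 3 probes opposite in sign, and Shank2 by 0.80, turning negative under normexp. Of 14 CA1 markers, 5 rose and none fell, with a median of 0.593 (also 5 when adjusted over the list alone). Among them, Man1a rose by 0.86, Pou3f1 by 1.37 and Mpped1 by 0.91. Of 20 neocortex and subiculum markers, 3 rose and none fell, with a median of 0.201. That list was not called (adjusted p = 0.143), and its median was 0.114 without NC 5 and 0.034 on the arrays with high Xist. It was called higher with slide as a block (median 1.26), under normexp, without NC 1, NC 2 and NC 4, and without NC 1 or HE 3 alone (0.305 and 0.387). Of 25 interneuron markers, 6 rose and 1 fell, with a median of 0.622, and the same numbers adjusted over the list alone. Sst, the somatostatin gene, rose by 0.91 ± 0.18 SE (adjusted p = 0.0138), Lamp5 by 1.28 and Cnr1, the cannabinoid receptor of cholecystokinin cells, by 1.05, whereas Pvalb, the parvalbumin gene, fell by 0.74 (adjusted p = 0.0216). The synaptic, CA1 and interneuron lists had adjusted p of 8.46e-07, 0.00186 and 0.00186 with the preset, and 0.572, 0.488 and 0.506 with an estimated correlation. Their medians within slide 2 were 0.750, 0.993 and 1.21. These rest on NC 5, which had the lowest array median in NC for each list (-0.592, -0.71 and -0.861). On the other NC arrays these ran from -0.23 to 0.114, -0.381 to -0.105 and -0.175 to -0.002. With the thalamic mean as a covariate the median log2 fold changes were 0.21, 0.565 and 0.33, and the interneuron list was not called. With slide as a block only Mpped1 (1.85) and Sst (1.42) of the genes named here passed, while Nlgn2, Dlg2 and Shank2 had 0.88, 1.16 and 1.40, Man1a and Pou3f1 0.98 and 1.89, and Lamp5, Cnr1 and Pvalb 2.27, 1.41 and -0.74. NC 5, the only NC array on slide 2, was the lowest NC array for Mpped1 (2.495) and Sst (3.27). Mpped1 did not pass without NC 2, NC 3 or any 1 HE array except HE 3 (0.86 to 0.98), Lamp5 without NC 2, NC 4, NC 5, HE 1, HE 2 or HE 4 (1.07 to 1.24), and Cnr1 without NC 2, NC 3, NC 5 or any 1 HE array except HE 4 (0.87 to 1.09).

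Lists on glutamate receptors, GABA, CA2 and CA3, and dentate granule cells, were not called. Of 24 glutamate receptors 1 rose and 3 fell (adjusted p = 0.264), and of 21 genes of GABA synthesis, transport and receptors 1 rose and 1 fell (adjusted p = 0.420). Of 19 CA2 and CA3 markers 2 rose and 2 fell (adjusted p = 0.996), and of 18 dentate granule cell markers 1 rose and 1 fell (adjusted p = 0.419). The GABA and the CA2 and CA3 lists had medians of -0.00688 and -0.102, although camera ranked them up. The GABA list was called higher under normexp (median 0.158, and 0.367 when centred), the glutamate list without NC 1 (0.258), and both the glutamate and dentate lists without NC 1, NC 2 and NC 4 (0.264 and 0.518), the dentate list also with slide and the Xist pattern together (0.553).

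Of 29 monoamine and acetylcholine receptors, 2 rose and 1 fell: Htr6, a serotonin receptor, rose by 1.11, turning negative under normexp, Chrm3, a muscarinic receptor, rose by 1.46, with 1 of 2 probes opposite, and Chrna4, a nicotinic subunit abundant in thalamus and midbrain, fell by 1.62 (adjusted p = 0.0110). Adra2c had a log2 fold change of 1.17 that did not pass (adjusted p = 0.0552). Of 14 genes of neurotrophin signalling and CREB, 3 rose and 1 fell. Besides Nptx2, Sort1 rose by 0.53 and Crem by 0.43, with 2 of 4 and 1 of 6 probes opposite in sign, and Creb1 fell by 0.34 (adjusted p = 0.0164). Of 22 circadian clock genes, 5 rose and 1 fell: the repressor Cry2 rose by 0.54 (adjusted p = 0.00642), Dbp by 0.57 and Npas2 by 0.87, turning negative under normexp, while the nuclear receptor Rora fell by 1.29 (adjusted p = 0.0136). Adjusted over the list alone, 2, 3 and 6 rose and 1 fell in each. Over all 20065 genes tested, 1369 rose, a share near that of the 2 of 29 receptors. Sort1 did not pass without NC 2, NC 5 or any 1 HE array (0.43 to 0.57), Crem without NC 2, NC 4, NC 5 or any 1 HE array except HE 4 (0.37 to 0.46), Dbp without NC 2, NC 4, NC 5, HE 3, HE 4 or HE 5 (0.47 to 0.61), and Npas2 without any 1 NC array except NC 1, or without HE 1, HE 3 or HE 5 (0.715 to 0.92). These 3 lists had adjusted p of 0.0157, 0.0298 and 0.00747 with the preset, and 0.479, 0.479 and 0.572 with an estimated correlation. Their medians of 0.397, 0.357 and 0.158 were 0.194, 0.384 and 0.283 within slide 2, and the receptor median was 0.253 without NC 4. None of the genes named here passed with slide as a block. Dbp and Chrm3 then had only 0.07 and 0.58, Htr6 and Chrna4 1.48 and -1.86, Sort1, Crem and Creb1 0.90, 0.59 and -0.35, and Cry2, Npas2 and Rora 0.60, 1.41 and -1.605. Under normexp centred on the median gene, the medians of the receptor and neurotrophin lists were -0.458 and 0.077. The receptor list kept its call in 16 of 22 alternatives and the neurotrophin list in 14, and both lost it with the thalamic mean, with slide and the Xist pattern together, and under centred normexp. The receptor list also lost it under normexp before centring, with slide as a block, and without NC 1, NC 2 and NC 4. The neurotrophin list also lost it with quantile normalization, the value table, probes above background on all arrays, high-Xist arrays alone, and without NC 5 (median 0.318). The clock list lost its call with the thalamic mean (0.127) and with slide and the Xist pattern together (0.073).

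Camera with the preset correlation called 14 of 36 lists, 8 higher and 6 lower, and none with an estimated correlation (smallest adjusted p = 0.479). Fry, which tests whether a list's genes move one way without comparing them with other genes, gave an adjusted p under 0.05 for the 7 lists on synapse, myelin, CA1, interneurons, receptors, neurotrophins and clock, but 0.0539 for the thalamic list. Of the remaining called lists, ribosomal proteins (12 of 78 fell, median -0.215) and oxidative phosphorylation (15 of 75 fell, 1 rose, median -0.186) had adjusted p of 9.45e-05 and 0.00186, and both were called higher instead under normexp. Interferon response and antigen presentation had 4 of 31 lower (median -0.372) and blood cell markers 2 of 15 lower (median -1.18), the latter not called without NC 4 (-1.04), NC 5 (-0.98) or HE 5 (-1.09). Immediate early genes had 2 of 28 higher (median 0.444) and striatum and basal forebrain markers 1 of 20 higher (median 0.668), the former median moving to 0.265 without NC 5 and the latter to 1.115 without HE 4. The striatal medians of single arrays overlapped, at -1.57 to 0.555 in NC and -1.16 to 1.87 in HE. Over all 20065 genes tested, 2661 were called lower and 1369 higher. The member counts of the interferon, blood, immediate early and striatal lists lie near those shares and do not by themselves set these lists apart. With the thalamic mean as a covariate the interferon, blood, immediate early and striatal lists were not called, with medians of -0.335, -0.643, -0.299 and -0.667. With slide and the Xist pattern together the interferon and striatal lists were not called (-0.06 and -0.972), nor were the ribosomal, oxidative phosphorylation and blood lists on the arrays with high Xist (-0.114, -0.116 and -0.931). In the former fit the pattern's effect rests on HE 3 against HE 4 and HE 5, and HE 3 had the highest striatal median (1.87). The blood list also lost its call with quantile normalization, the value table and probes above background on all arrays. Adjusted over the list alone, 6 ribosomal, 18 oxidative phosphorylation, 3 interferon and 6 blood genes fell, and 2 oxidative phosphorylation, 1 immediate early and 0 striatal genes rose. The adjusted p of these 6 lists was 0.768 with an estimated correlation. Astrocyte, microglia and neurogenesis lists were not called, but the microglia list was called higher without NC 3 (median 0.179) and under normexp (0.017). The neurogenesis list was called higher without HE 3 (0.165), and with slide as a block, alone (0.302) or with the Xist pattern added (0.77). Gfap, the astrocyte filament gene, had a log2 fold change of -0.72 ± 0.33 SE (adjusted p = 0.137). Choroid plexus markers differed widely between single arrays of both groups and were not called, except as higher with slide as a block (median 1.82, also with the Xist pattern added), with the thalamic mean, or without NC 3 (1.09), HE 3 (0.83) or HE 5 (0.88). Ttr, the transthyretin gene of choroid plexus, was 0.68 ± 2.27 (SD, n = 5) in NC and 1.49 ± 2.38 in HE (adjusted p = 0.693).

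Of 18 measured receptors and coregulators of estrogen and other sex steroids, 2 rose and 2 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.161), except as higher without NC 1, NC 2 and NC 4 (median 0.288). Its median was 0.198 and its mean -0.0116. Esrrg and Esrrb, orphan receptors related to the estrogen receptors that do not bind estradiol, fell by 0.78 ± 0.10 SE (adjusted p = 0.00463) and by 1.41 ± 0.21 (adjusted p = 0.00718). Nrip1, a corepressor of nuclear receptors, rose by 0.52 (adjusted p = 0.0206), with 1 of 3 probes opposite in sign, and Phb2, prohibitin 2, by 0.26 (adjusted p = 0.0469), passing in only 9 of 28 alternatives. Nrip1 did not pass without NC 2 (0.50), nor Phb2 without any 1 array except NC 4 (0.23 to 0.29). The estrogen receptor gene Esr1 had a log2 fold change of -0.22 ± 0.43 SE (adjusted p = 0.750), but passed as lower under normexp (-1.21, and -1.0 when centred). Esr2 was not well above background on any array. Cyp19a1, the aromatase gene, had 0.57 ± 0.29 (adjusted p = 0.185), with 3 of 5 NC arrays well above background. Leaving out 1 array moved it from 0.373 (without HE 5) to 0.735 (without HE 2). Bdnf, the brain-derived neurotrophic factor gene, had 0.40 ± 0.19 (adjusted p = 0.157). With slide as a block, none of Esrrg, Esrrb, Nrip1 and Phb2 passed, with log2 fold changes of -1.02, -1.37, 0.48 and 0.34. The estradiol-induced genes of peripheral tissue were not called either (2 of 19 higher, 1 lower, the same adjusted over the list alone, adjusted p = 0.548), with a median of -0.127 although camera ranked them up.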

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

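Among 144 sets of 4 or 5 arrays of a group, 8 held an array far from the rest of its group, where chance gives about 1 in 20. Xist was -4.53 on NC 5, against 3.73 to 4.44 on the other NC arrays, which is the pattern of Y-linked signals described above. Sst was 3.27 on NC 5, against 4.03 to 4.15, and Htr6 was -5.55 on NC 5, against -4.95 to -4.73. Tcf7l2 was 1.76 on HE 4, against -0.35 to -0.04 on the other HE arrays. Apoa2 was -7.39 on NC 3, against -2.46 to -1.39. Grap2 was -6.08 on NC 1, against -8.74 to -8.00, and Nrip1 was 1.25 on NC 1, against 0.68 to 0.77. Sult3a1 was -7.26 on HE 1, against -9.53 to -8.92, all below background.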

How the results depend on the processing

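The count of 4030 genes kept its size within 1.5 times with slide as a random block (4322, correlation between arrays of a slide -0.025), quantile normalization (4305), the value table (4299), no filter on dim probes (3319), probes above background on all arrays (3870), the mean over probes (4373) and a trend with robust prior (4506). It was 185 with slide as a fixed block, 0 on the 3 slide 2 arrays (limma; 7161 at an unadjusted p under 0.05), 8725 with normexp and 7109 with probes tested one by one. The median of all genes was -0.282 with normexp, against -0.043; centred on the median gene, normexp called 8846. Leaving out 1 array gave 1914 to 4183 genes and 12 to 18 lists; the count moved by over 1.5 times without NC 2 (1914), HE 1 (2010) or NC 5 (2236). The replicate block gave 2976 genes and 14 lists. Same-numbered arrays had deviations correlating at -0.077 to 0.13, over 0.1 for 2 of 5 pairs, and 4 of 10 arrays correlated best with their own number. These values do not settle whether the numbers pair the arrays. Of the alternatives chosen after seeing the data, the Xist and Y-linked pattern as a covariate gave 4479 genes, the arrays with high Xist 96, slide as a block with this pattern 3 (limma; 2900 at an unadjusted p under 0.05), the arrays without high liver transcripts 2007, and the thalamic mean as a covariate 1 gene and 8 lists. With 4 against 3 arrays fewer genes pass by construction: leaving out 1 NC and 2 HE arrays in all 50 ways gave 0 to 2007, median 291.5, and a median of 73.5 for the ways that leave out NC 5, as the high-Xist arrays do. The 14 called lists became 0 with an estimated correlation and 7 with fry. The list counts that follow leave both of these tests out, since all 22 alternatives used camera with its preset correlation. Over 22 alternatives, the synaptic and CA1 lists kept their calls in 22, the myelin, interneuron and immediate early lists in 21, the thalamic, clock, interferon and striatal lists in 20, the ribosomal and oxidative phosphorylation lists in 19, the receptor list in 16, and the neurotrophin and blood lists in 14. With the thalamic mean as a covariate the immediate early and striatal medians turned to -0.299 and -0.667, not called. The causes of the other moves were not tested.

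Signs turned under normexp, first uncentred and then centred, for Snai3 (-1.17, -0.96), Grap2 (-1.21, -1.0), Tmem45b (-1.25, -1.04), Acvrl1 (-0.39, -0.18), Htr6 (-0.70, -0.49), Shank2 (-0.66, -0.45), Npas2 (-0.49, -0.28) and Cyp19a1 (-1.24, -1.025), and for Pnlip before centring (-0.16). Slide as a block, equal to slide 2 alone, turned Cyp19a1 (-0.08) and Xist (7.95); with the Xist and Y-linked pattern added it turned Phex (-0.24). Esr1 turned with quantile normalization (0.044), the value table (0.054) and the thalamic mean as a covariate (0.047), and ranged from -0.53 without NC 1 to 0.006 without NC 2; it passed as lower with normexp (-1.21; centred -1.0). Gfap turned with the thalamic mean (0.19) and Ttr without high liver transcripts (-0.735). None of these turned values passed the test, and the cause was not tested. Among called genes, those that passed in the same direction in fewer than 14 of 28 alternatives included Phb2 (9), Slc6a3 and Acvrl1 (11), Npas2 (12), and Sort1 and Crem (13). Ambp passed in 12 of 26, Snai3 in 11 of 27 and Tmem45b in 8 of 22. Not called, Adra2c passed in 7 of 28 and Bdnf in 1 of 28.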

Other observations

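The slide and Xist tests below were chosen after the result was seen. The further gene lists were written after liver and midbrain transcripts had been noticed, but before the values of their members were seen.

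Immunoglobulin heavy chain probes were singled out after their values were seen. A probe for the gamma 2C constant region (chromosome 12, 114525673 to 114525732, mm9) was not well above background on any NC array, at -8.36 ± 0.28 (SD, n = 5), and was -2.72 ± 0.59 in HE, at least 12.2-fold higher (adjusted p = 2.21e-05). A probe for the mu constant region (chromosome 12, 114659100 to 114659159) rose from -1.03 ± 0.79 to 2.0 ± 0.33 (adjusted p = 0.00322), and another probe of that transcript from -4.05 to -1.41; with slide as a block the first differed by 3.85. A second gamma 2C probe differed by only 0.778 and the Ighm probe by 0.512. Over the alternatives, the fitted log2 fold change of the gamma 2C gene ranged from 0.516 with normexp to 6.27, and its adjusted p from 5.41e-06 to 0.485. Without any 1 HE array the second probe was the brighter and stood for the gene, which then did not pass (0.685 to 0.841).

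Pituitary hormone transcripts were high on NC 1, NC 2 and NC 4, the arrays with high liver transcripts, and on HE 3. Prl, the prolactin gene, was 1.49, 1.89, 3.34 and 2.24 there, against -4.08 and -3.55 on NC 3 and NC 5 and -6.48 to -0.77 on the other HE arrays. Gh, the growth hormone gene, was -2.66, -2.70, -1.45 and -1.56, against -7.26 and -6.80 on NC 3 and NC 5. Neither passed (adjusted p = 0.302 and 0.689). The median of choroid plexus markers ranged from -1.33 to 2.09 in NC and from -1.63 to 1.91 in HE.

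The count of genes that differ between HE and NC is not one that grouping by chance gives: of 100 splits of the 10 arrays into 5 and 5, only the real one (1 of 100) reached 4030 genes, and the highest other called 3. The unequal numbers of high-Xist arrays are argued against as the whole cause, since 4479 genes passed with the pattern as a covariate, while the pattern itself called 4 genes. Slide cannot be told apart from the group for most genes. Of 70 genes called from slides 1 and 3 alone, 95.7% had the same sign on slide 2 (median size 1.40 there and 1.12 on slide 2), but slide 2 holds a single NC array, and with slide and the Xist pattern in the fit 3 genes passed. In that last fit the pattern's effect comes from slide 3 alone, as HE 3 against HE 4 and HE 5. The maternal treatment, the litter and the dissection also differ or may differ with the group, and wrong sex labels or an exchange of samples were not tested, so these stay open.

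Lower thalamic and midbrain transcripts in HE may reflect neighbouring brain tissue in unequal amounts between samples. A further list of 39 midbrain, hypothalamic and hindbrain genes had 29 measured members with a median log2 fold change of -0.585. Of these, 22 were lower and 8 were called lower, among them Gata2 (-1.64), Tal1 (-2.62), Lhx1 (-2.45) and En2 (-1.35). The median deviation of this list was 0.88, 0.26 and 1.021 on NC 2, NC 4 and NC 5. On NC 1 and NC 3 it was -0.178 and -0.41, within the HE range of -0.673 to 0.015. The thalamic list was instead highest on NC 5 (1.233) and NC 3 (1.043), and lower on NC 2 (-0.161) than on HE 4 (0.196). Other transcripts of these regions were uneven within NC: Slc6a3 was 4.88 and Ddc 3.15 on NC 2, against -2.36 and 0.17 on NC 3, whereas Hcrt was 2.06 on NC 3 and -1.42 on NC 2. Adding the thalamic mean to the fit left 1 gene and 8 lists, the myelin list (median -0.49) among them, but that mean itself differs between the groups, so this does not part tissue content from a response to treatment. A lower expression of these genes within hippocampal cells of HE offspring was not tested and stays open. With the thalamic mean as a covariate, the synaptic and interneuron medians given above were smaller, while the CA1 median was 0.565 against 0.593. Whether unequal tissue also bears on the synaptic, CA1, interneuron and myelin differences was not tested and stays open.

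Liver transcripts on NC 1, NC 2 and NC 4 may come from liver RNA carried into single samples. Of 33 measured genes of a further list of 50 liver genes, 12 (36.4%, where chance gives 0.83%) had exactly these 3 arrays highest, which lies between the shares set in advance for and against this explanation, so carried-over RNA stays open. Alb and Ahsg were 0.50 and 0.45 on NC 1, against -7.93 and -7.61 on NC 3. A difference between the groups as a whole also stays open: NC 3 or NC 5 lay at or below the highest HE array for 30 of the 33 genes (90.9%), but genes without any difference give 95.2%, so the bound set in advance was too low for this share to exclude it. Brain also expresses part of these genes, which was not counted here, and 5 of the 33 were called lower and 1 higher in HE.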
